A study of Sus scrofa with 2 samples.

How the data were processed

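The series holds single-nucleus RNA sequencing of frozen left ventricular free wall from Bama pigs after 12 months of a high-fat, high-sucrose diet, with 1 wild-type library (WT) and 1 triple-transgenic library (TG). Nuclei were recovered through an iodixanol gradient and libraries made with the 10x Genomics Chromium 3' v3.1 chemistry, per the labels' protocols. Per the submitters' processing notes, reads were aligned to Sscrofa11.1 and processed with Cell Ranger 3.1.0 and Seurat 3.1.1. Per the file headers, the matrices came from Cell Ranger 5.0.0, and this difference was not resolved. The values used are deposited counts of unique molecular identifiers (UMIs), 1 matrix per library with 31908 genes. Symbols in the matrices covered 16498 genes, and a reference table of Ensembl names added 841 of the 15410 others. Empty droplets were not used here, so free RNA was judged from the nuclei themselves.

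Nuclei were kept with at least 500 genes and at most 5% of UMIs from the 13 mitochondrially encoded genes, and genes with counts in at least 3 nuclei. This left 16725 of 18251 barcodes in WT and 14939 of 15000 in TG, with median UMIs of 5442 and 3937 and median mitochondrial shares of 0.446% and 0.577%. Of the barcodes left out, 943 in WT and 1 in TG had too few genes, and 812 and 60 too high a mitochondrial share. Counts were scaled per nucleus and log-transformed, and both libraries were clustered together (scanpy 1.11.5, Python 3.11.15) on 2000 variable genes, 30 principal components and 15 neighbours. Clusters came from the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 with seed 1, without batch correction. Scrublet, run per library as part of scanpy with an expected rate of 0.06, marked 1163 nuclei (6.95%) as doublets in WT and 0 in TG. Because it failed in one library, its marks were not used, and clusters with markers of unrelated classes were set aside in both libraries instead.

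A cluster took the name of a class when at least 60% of that class's markers, and at least 3, reached 20 CPM and a log2 fold of 1 over a baseline, the 25th percentile of clusters with at least 40 nuclei. At least 3 of its 100 leading genes had to be markers of the class. A cluster counted as mixed when markers of an unrelated class reached a mean log2 fold of 3, or 1.5 with a mean Scrublet score 3 times the median of the library. The baseline and these thresholds were set after the clusters had been seen. They left 7.05% of WT and 16.2% of TG nuclei mixed, and 2.63% and 1.86% unnamed. Names end in "-like" because they rest on transcripts alone. The filters, the comparisons, most alternatives and the gene lists were fixed before the data were examined.

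For each class with at least 100 nuclei in both libraries, counts were summed over nuclei and given as counts per 1000000 nuclear-encoded UMIs (CPM). Shares carry exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios intervals from the conditional binomial distribution, all at 95% (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). These intervals hold the precision that depth allows and leave out differences between animals and any further spread between nuclei. No p-values were computed, since library and genotype are the same split. A gene with 0 counts in one library was given as "at least" a ratio, against the limit of 3 counts that a count of 0 allows.

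Genes were named by a fixed rule. Each had to reach 50 CPM in one library and 25% of its highest level over classes. The 12 highest and 12 lowest in TG, ordered by the bound of the interval nearest to no difference, were named in the 3 largest classes, and 4 of each in the others. Genes fixed beforehand and the members furthest apart of selected gene lists were named as well, and those lists were selected after their results had been seen. Some genes that these rules picked are not reported here. Genes without a symbol in the matrices, ribosomal protein genes and genes read for sex were left out of this ranking. Of 51 fixed lists with 875 genes, 788 genes were in the matrices. For a list, genes with at least 20 UMIs over both libraries counted as measured, and at least 5 were needed. The median log2 ratio of members, with 0.5 added to each count, was placed among 10000 random lists matched on mean CPM in 20 bins. A list stood apart below percentile 1 or above percentile 99. A member counted as higher or lower at a ratio of at least 1.5 with an interval that left out 1. With 24 function lists, 214 pairs of list and class were looked at and 85 stood apart. Correlation between genes was not modelled, so a percentile is a place among random lists and not an error rate.

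Alternatives changed the filters, the clustering, the scaling (TMM factors from edgeR 4.0.16 in R 4.3.3 among them), the weighting and depth of nuclei, and the treatment of mixed clusters and free RNA. The last took off a library-wide profile at the share that explains the cardiomyocyte markers in a class. Alternatives with a floor of 2000 UMIs, with named nuclei as denominator, without the top 6% of Scrublet scores, or without the most abundant gene in the denominator were added after the data had been seen. The procedure was tested on simulated data, Poisson counts drawn at the depth of each library from the pooled profile of a class, with 100 genes set at each known ratio. In cardiomyocyte-like nuclei 100.0% of genes set at 1.5 times were recovered, 95.9% of intervals covered the true value, and 1 of 20 unmoved lists stood apart. In macrophage-like nuclei these values were 98.0%, 96.1% and 0 of 20. The simulated counts follow the model behind the intervals, so this checks the computation and not the spread between nuclei or animals. Figures were drawn with matplotlib 3.10.9. NPPA and MYH6 were not analysed here, as the gene table lists neither symbol.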

Results

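Single-nucleus RNA sequencing measured transcripts in nuclei from the left ventricular free wall of Bama pigs, a Chinese miniature breed, after 12 months on a diet rich in fat and sucrose. One library came from wild-type tissue (WT) and the other from triple-transgenic tissue (TG) carrying a variant of the lipase gene PNPLA3, a dominant-negative receptor for the gut hormone GIP (GIPR) and human IAPP, the islet amyloid peptide. The question put by the series is how the cell classes of the ventricle differ between these genotypes under the same diet. The WT library held 18251 barcodes with 127126477 UMIs (counted RNA molecules), of which 16725 nuclei were kept, with a median of 5442 UMIs and 2322 genes. The TG library held 15000 barcodes with 89324966 UMIs, of which 14939 nuclei were kept, with a median of 3937 UMIs and 1944 genes. The lowest total among barcodes was 500 UMIs in WT and 3.94 times that in TG, and 3077 WT barcodes against 175 TG barcodes lay under 2000 UMIs. With 1 library per genotype there was no replicate check and no test between genotypes. Every difference given here is between these libraries, and all intervals are 95% intervals of counting error only.

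Cardiomyocyte-like nuclei were the most frequent class in both libraries, and vascular endothelial-like nuclei took about 2 times the share in TG that they took in WT. Vascular endothelial-like nuclei, which line blood vessels, made up 9.31% of WT nuclei (exact Clopper-Pearson interval 8.87% to 9.76%) and 18.9% of TG nuclei (18.3% to 19.5%), a ratio of 2.03 (1.92 to 2.15). Macrophage-like nuclei, the resident phagocytes, stood at 8.61% in WT (8.19% to 9.05%) and 3.36% in TG (3.08% to 3.66%), a ratio of 0.390. Cardiomyocyte-like nuclei took 41.5% and 36.0%, and fibroblast-like nuclei, which make the matrix, 17.3% and 13.3%. Lymphatic endothelial-like nuclei took 5.73% of WT and 4.02% of TG, and T or NK lymphocyte-like nuclei 3.22% and 2.36%. Smooth muscle-like nuclei were at 1.60% and 1.14%. Pericyte-like nuclei, which wrap capillaries, had shares of 2.03% and 2.02%, and Schwann or neural-like nuclei 0.999% and 0.870%, in each case alike within counting error. With at least 2000 UMIs asked of both libraries the pericyte ratio was 1.27 (1.07 to 1.51). Clusters 23 and 26, also led by pericyte genes but set aside as mixed, held 28 and 43 WT nuclei and 115 and 89 TG nuclei. The pericyte shares thus leave out more such nuclei in TG than in WT. Clusters with markers of unrelated classes, set aside as mixed, held 7.05% of WT and 16.2% of TG nuclei, and unnamed clusters 2.63% and 1.86%. With the mixed nuclei counted in the class whose markers scored highest in their cluster, the macrophage ratio was 0.699. Counted this way, cluster 23 went to vascular endothelium and cluster 26 to fibroblasts, although pericyte genes lead both. Cluster 12, led by fat cell genes, went to fibroblasts. With genes scaled within each library, the T or NK ratio turned to 1.02 and the pericyte ratio was 1.49.

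**Figure D1:**
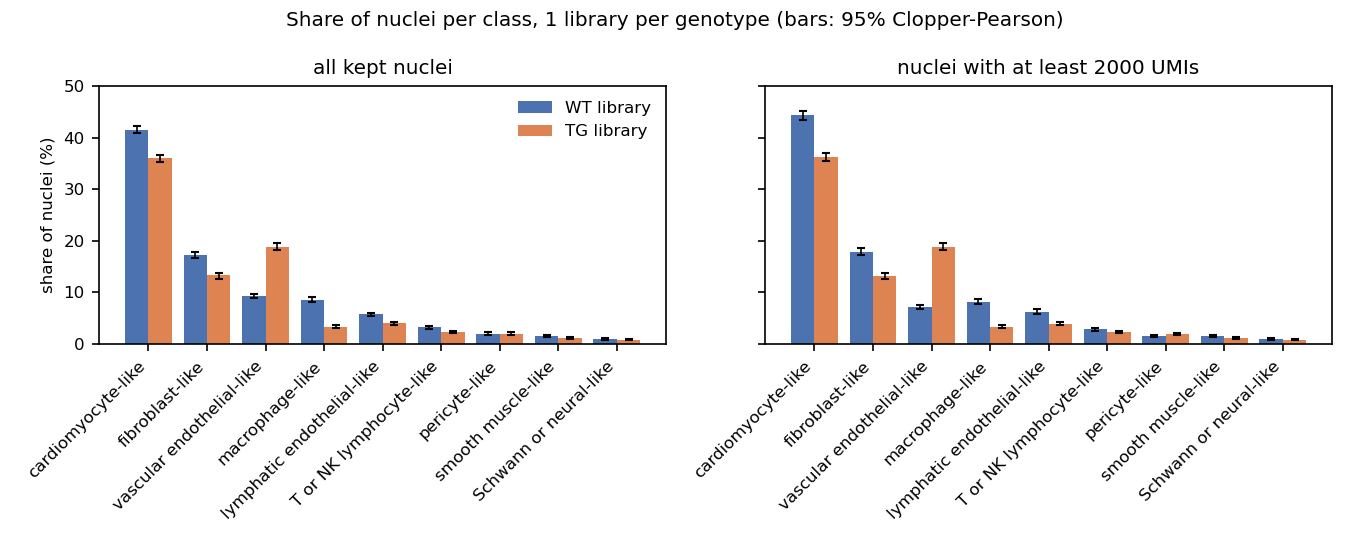
Share of nuclei (%, vertical axis) per cell class in the WT and TG libraries (bar colours), over all kept nuclei on the left and over nuclei with at least 2000 UMIs on the right. Error bars are exact 95% binomial intervals. The vascular endothelial-like bars go from 9.31% in WT to 18.9% in TG over all nuclei, and from 7.11% to 18.8% at 2000 UMIs.

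Transcripts of heart muscle were found in every class, and MYL2, MYH7 and NDUFA4 were higher in TG in each of the 8 classes outside cardiomyocytes. MYL2, the regulatory light chain of ventricular myosin, measured 776 counts per 1000000 nuclear-encoded counts (CPM) in WT and 2617 CPM in TG fibroblast-like nuclei, and 785 and 2414 CPM in macrophage-like nuclei. In cardiomyocyte-like nuclei MYL2 was at 2035 CPM in WT (Poisson interval 2025 to 2045) and 1477 CPM in TG, less than in the TG fibroblast-like nuclei. MYH7, the slow myosin heavy chain, was at 4317 CPM in T or NK nuclei of TG and at 2830 CPM in cardiomyocytes of TG. NDUFA4, a subunit of the respiratory chain, lay between 475 and 524 CPM over the fibroblast, vascular endothelial, macrophage, lymphatic and T or NK nuclei of TG, and between 139 and 192 CPM in WT. Transcripts of the large, intron-rich genes RYR2, the calcium release channel, and CTNNA3, an alpha-catenin, lay further below their cardiomyocyte levels in fibroblast-like nuclei. RYR2 was at 15991 CPM in TG cardiomyocytes and at 523 CPM in WT and 869 CPM in TG fibroblast-like nuclei, and CTNNA3 at 7260 CPM and at 171 and 324 CPM. RYR2 was likewise higher in TG in vascular endothelial (507 and 701 CPM), macrophage (330 and 669), lymphatic endothelial (322 and 480), T or NK (405 and 709) and pericyte-like nuclei (6743 and 10497). CTNNA3 was at 88.0 and 203 CPM in macrophage-like and 164 and 430 CPM in T or NK-like nuclei. In smooth muscle-like nuclei RYR2 was lower in TG, at 6226 CPM in WT and 3250 CPM in TG, and in Schwann or neural-like nuclei it was at 4965 and 4686 CPM. The median level of cardiomyocyte markers in fibroblast-like nuclei was 17.8% of that in cardiomyocytes in WT and 51.1% in TG. For macrophage-like nuclei these values were 16.6% and 50.4%, for vascular endothelial-like nuclei 22.4% and 43.1%, and for pericyte-like nuclei 47.6% and 83.1%. Free RNA in droplets is counted in nuclei that do not make it, so these levels stand beside every comparison outside cardiomyocytes. In TG pericyte-like nuclei, RYR2 (10497 CPM) and CTNNA3 (5355 CPM) lay far above the fibroblast-like levels, while MYL2 (1854 CPM) lay below. An even share of free RNA would not give this pattern. In WT pericyte-like nuclei RYR2 and CTNNA3 were also above the fibroblast-like levels, at 6743 and 3643 CPM. In smooth muscle-like nuclei CTNNA3 was at 6824 CPM in WT and 8652 CPM in TG, against 8390 and 7260 CPM in cardiomyocytes. Droplets that also hold a cardiomyocyte nucleus are not excluded in pericyte-like nuclei, and expression by these classes themselves was not tested.

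**Figure D2:**
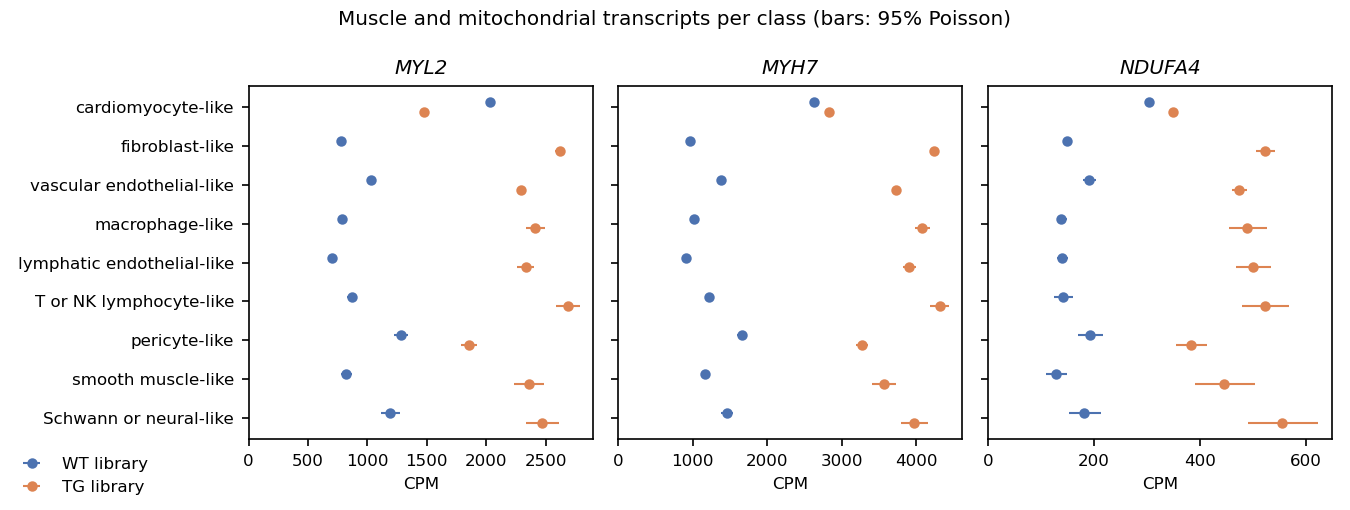
CPM (horizontal axes) of MYL2, MYH7 and NDUFA4 in each cell class (vertical axis) of the WT and TG libraries (point colours), with exact 95% Poisson intervals as bars. In TG the levels of the 5 classes from fibroblast-like to T or NK-like lie close together, from 2292 to 2689 CPM for MYL2, above the 1477 CPM of cardiomyocytes.

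Gene lists of muscle and mitochondria followed the same division. Of the 43 measured members of the nuclear-encoded respiratory chain (OXPHOS), 37 were higher in TG by at least 1.5 times in fibroblast-like nuclei, 0 lower and 6 neither, with a median log2 ratio of 1.10. In macrophage-like nuclei 39 members were higher, 0 lower and 4 neither (median 1.10), and in vascular endothelial-like nuclei 23, 0 and 20 (median 0.59). In cardiomyocyte-like nuclei 0 were higher, 2 lower and 41 neither (median -0.10, percentile 55.87). The most abundant gene, ENSSSCG00000048856, took 6.36% of WT and 13.9% of TG counts in cardiomyocyte-like nuclei. By construction this lowers the CPM of all other genes there in TG. OXPHOS stood above percentile 99 of random lists matched on level in all 8 classes other than cardiomyocytes, with medians from 0.41 to 1.13. With a library-wide profile subtracted, the pericyte median turned to -0.25, percentile 80.76. Sarcomere genes had 22 higher, 0 lower and 1 neither of 23 in fibroblast-like nuclei (median 1.43), and in cardiomyocytes 0, 3 and 20 (median -0.30). In smooth muscle-like nuclei they split, with 8 higher, 7 lower and 7 neither (median 0.24, percentile 97.88). Over the fibroblast, vascular endothelial, macrophage, lymphatic and T or NK nuclei of TG, the median OXPHOS gene was 1.29 times as high in its highest as in its lowest class, and the median sarcomere gene 1.24 times. For interferon response genes this ratio was 6.51, and for extracellular matrix genes 29.89. Even levels were not particular to TG or to muscle genes. In WT the ratio was 1.49 for OXPHOS and 1.53 for sarcomere genes, and in TG it was 1.71 for unfolded protein response genes. The fatty acid oxidation list (1.55) and the pyruvate and TCA cycle list (1.39) were also alike over these classes. Both stood above percentile 99 in the 8 classes, with medians from 0.39 to 0.75 and from 0.21 to 0.72. On that subtraction the fatty acid list was at -0.15, 0.04, 0.16, -0.38 and 0.43 in lymphatic, macrophage, T or NK, pericyte and Schwann or neural-like nuclei, and the TCA cycle list at 0.05, 0.24, 0.22, -1.44 and 0.29, none of them above percentile 99. The TCA cycle list was at 0.37, percentile 98.92, in fibroblast-like nuclei. When each library was clustered on its own, the fatty acid list was at 0.06, 0.21 and 0.07 in vascular endothelial, macrophage and T or NK-like nuclei, and the TCA cycle list at 0.07, 0.27 and 0.10.

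**Figure D3:**
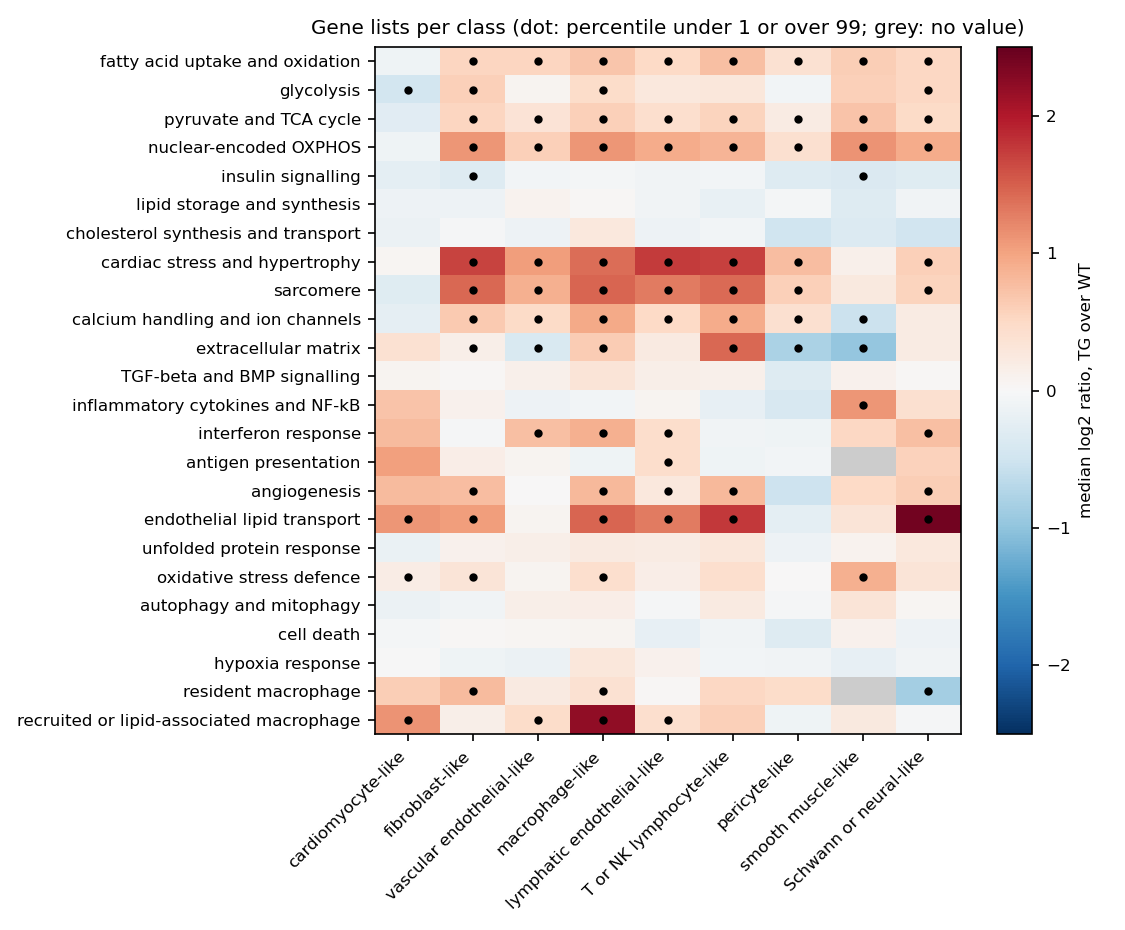
Median log2 ratio, TG over WT (colour), of 24 gene lists (vertical axis) in 9 cell classes (horizontal axis); a dot marks a median below percentile 1 or above percentile 99 of 10000 random lists matched on level, and grey a list with too few measured members. The OXPHOS row carries dots in 8 classes and none in cardiomyocytes.

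The pig genes that match the transgenes had few counts. PNPLA3 (ENSSSCG00000027266) had 34 UMIs in the named nuclei of WT, 0.312 CPM (Poisson interval 0.216 to 0.436), and 42 in TG, 0.609 CPM (0.439 to 0.823). GIPR (ENSSSCG00000021053) had 12 and 6 UMIs, 0.110 CPM (0.0569 to 0.192) and 0.0870 CPM (0.0319 to 0.189). IAPP (ENSSSCG00000000582) had 9 UMIs in WT, 0.0826 CPM (0.0378 to 0.157), and 32 in TG, 0.464 CPM (0.317 to 0.655). PNPLA3 and IAPP were thus higher in TG beyond counting error and GIPR was not distinguishable at this depth. These levels were pooled over classes whose shares differ between the libraries, so the mix of classes is not excluded as a source. Whether transcripts of the transgenes align to these pig genes was not determined, so the counts do not check the labels.

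Cardiomyocyte-like nuclei of the 2 libraries stood far apart in ADAMTS19, LRP1B and FBLN5. ADAMTS19, a secreted metalloprotease (chromosome 2, 132145266 to 132413116, Sscrofa11.1), measured 1.03 CPM in WT and 72.9 CPM in TG, 70.5 times higher in TG (56.4 to 89.5), a log2 ratio of 6.14 that came to 5.34 with nuclei thinned to 1000 UMIs. LRP1B, a large receptor of the LDL receptor family (chromosome 15, 9612805 to 11499969), was at 88.0 and 1805 CPM, 20.5 times higher, a log2 ratio of 4.36 (4.32 to 4.39). The synaptic adhesion gene NRXN3 was at 11.4 and 215 CPM, and the glutamate receptor subunits GRIA1 and GRIK1 at 24.7 and 406 CPM and at 13.1 and 114 CPM. PDK4, which blocks pyruvate entry into the mitochondrial TCA cycle (chromosome 9, 75246956 to 75260134), was at 49.5 CPM in WT and 371 CPM in TG, 7.49 times higher (7.23 to 7.77). Also higher in TG were FRZB, a Wnt antagonist (5.06 and 67.4 CPM), SYT14 (6.89 and 80.2), the netrin receptor UNC5C (20.4 and 222), SMIM2 (5.93 and 63.3), the protease TLL2 (9.28 and 78.9) and the condensin subunit SMC2 (10.8 and 80.7). Lower in TG was FBLN5, an elastic fibre protein (chromosome 7, 113423629 to 113526412), at 301 CPM in WT and 7.13 CPM in TG, 42.2 times higher in WT. NREP was at 141 and 14.0 CPM. The immediate early nuclear receptors NR4A1 and NR4A3 were at 196 and 26.1 CPM and at 487 and 80.2 CPM. ROBO2, an axon guidance receptor, was at 2516 and 423 CPM, and ACTC1, cardiac alpha-actin, at 506 and 139 CPM. The heparan sulfate enzyme NDST3 (189 and 25.4 CPM), the glycosyltransferase GALNT10 (222 and 48.0), NMD3 (263 and 67.3), AFF1 (539 and 156), ASB18 (212 and 61.0) and LGR4 (99.4 and 28.1) were lower in TG as well.

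Among the lists, glycolysis was lower in TG cardiomyocytes, with a median log2 ratio of -0.46, below percentile 1. Of 19 measured members 1 was higher, 7 lower and 11 neither. HK2, which traps glucose in the cell, measured 4.26 CPM in WT and 1.17 in TG, GAPDH 364 and 170, the aldolase ALDOA 16.7 and 8.15, and the enolase ENO3 119 and 65.5. Fatty acid oxidation had 2 members higher, 2 lower and 22 neither (median -0.11, percentile 51.07). Oxidative stress defence was higher, with 5 of 22 members higher, 1 lower and 16 neither (median 0.19). Its members furthest apart were MGST1, a microsomal glutathione transferase, at 108 and 229 CPM, GCLC, the first enzyme of glutathione synthesis, at 17.8 and 31.0 CPM, SOD3 at 0.715 and 1.79 CPM, and PRDX3 with 27.6 CPM in WT and 16.4 in TG. With each nucleus weighted equally this list's median was 0.14, at percentile 98.7. Clock genes, which follow the time of sampling, had 2 members higher, 4 lower and 11 neither (median -0.34), and ARNTL, the partner of CLOCK, was at 88.9 and 31.9 CPM. TEF was at 14.3 and 5.14 CPM and BHLHE40 at 14.5 and 8.17 CPM, with a log2 ratio of -0.14 in thinned nuclei. Glucocorticoid and fasting genes had 5 higher, 3 lower and 9 neither of 17 (median -0.06, percentile 58.12). Outside cardiomyocytes this list stood above percentile 99 in vascular endothelial (6 of 17 higher, 1 lower, 10 neither, median 0.20), macrophage (7 of 17, 0 and 10, 0.45), lymphatic endothelial (5 of 17, 2 and 10, 0.24) and T or NK-like nuclei (9 of 15, 1 and 5, 0.67). With the library-wide profile subtracted it was at -0.03, 0.32, -0.17 and -0.63 there. Immediate early and heat shock genes, which follow handling, had 2 higher, 4 lower and 16 neither (median -0.34). The transcription factors ATF3 and FOS measured 37.8 and 3.44 CPM and 12.3 and 3.56 CPM, and FOSB had 134 UMIs in WT and 1 in TG. Markers of other classes were also higher in TG cardiomyocytes, with 13 of 15 vascular endothelial markers higher, 0 lower and 2 neither (median 1.22) and 9 of 14 fibroblast markers, 0 and 5 (median 1.20). The lists of endothelial lipid transport (8 of 15 higher, 0 lower, 7 neither, median 1.11) and of lipid-associated macrophages (6 of 11 higher, 0 lower, 5 neither, median 1.13) moved with those markers, and the macrophage list came to 0.50, percentile 96.86, in thinned nuclei. Most WT cardiomyocytes came from clusters 0 and 3 and most TG cardiomyocytes from clusters 17 and 25, with cluster 6 in both. LRP1B and GRIA1 lead clusters 17 and 25, and ROBO2 and NR4A3 lead cluster 3.

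**Figure D4:**
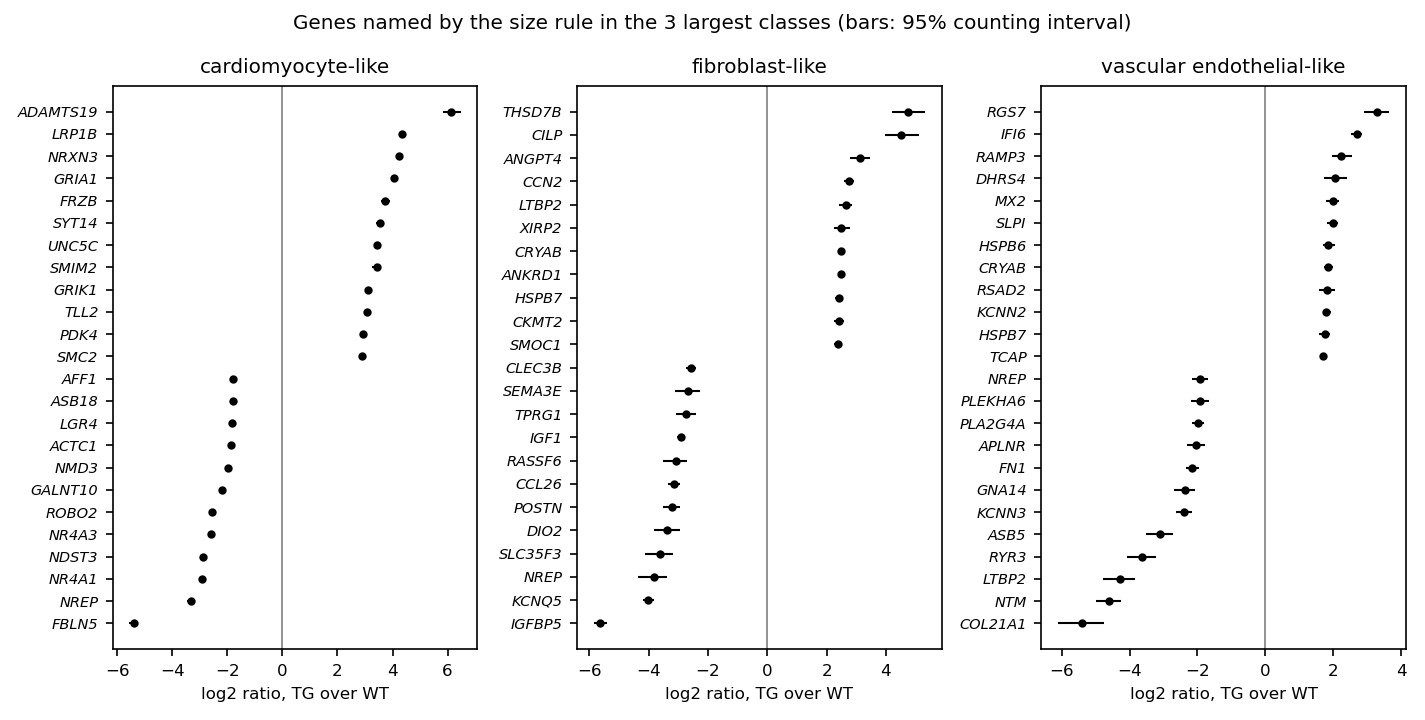
Log2 ratio, TG over WT (horizontal axis), of up to 12 genes highest and 12 lowest in TG (vertical axis) in the 3 largest cell classes, with 95% counting intervals as bars. ADAMTS19 leads cardiomyocytes at 6.14, and IGFBP5 is lowest in fibroblast-like nuclei at -5.64.

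Fibroblast-like nuclei stood far apart in IGFBP5 and IGF1, lower in TG, and in CCN2 and LTBP2, higher in TG. IGFBP5, which binds insulin-like growth factors (chromosome 15, 118861816 to 118877787), was at 1542 CPM in WT and 31.0 CPM in TG, 49.8 times higher in WT. Its ligand gene IGF1 was at 594 and 78.8 CPM, and POSTN, periostin, a protein of remodelling matrix, was 9.37 times higher in WT. CCN2, a matricellular growth factor, was at 27.6 CPM in WT and 186 CPM in TG, 6.73 times higher in TG, and LTBP2, a binder of latent TGF-beta, at 18.5 and 115 CPM. CILP, a cartilage matrix protein, was at 2.35 and 53.7 CPM, THSD7B at 2.51 and 67.3 (log2 ratio 4.74, and 2.53 with each library clustered on its own), the angiopoietin ANGPT4 at 7.62 and 66.3, and SMOC1 at 62.5 and 323. Lower in TG were the potassium channel KCNQ5 (701 and 43.3 CPM), NREP (91.5 and 6.41), SLC35F3 (86.0 and 6.92), the deiodinase DIO2 (82.6 and 7.96), the chemokine CCL26 (320 and 36.2), RASSF6 (81.0 and 9.52), TPRG1 (94.3 and 14.0), CLEC3B (292 and 49.0) and SEMA3E (6.42 times higher in WT). The muscle genes CRYAB, ANKRD1, HSPB7, CKMT2 and XIRP2 also met the rule, but their levels in TG were alike over the 5 classes named above. ANKRD1, for example, was at 579 CPM in TG fibroblast-like nuclei and between 494 and 598 CPM over those classes. Extracellular matrix genes split, with 14 of 41 members higher, 10 lower and 17 neither (median 0.14). TNC, tenascin C (2.43 and 37.4 CPM), and MEOX1, a transcription factor gene on this list (0.810 and 19.4 CPM), were higher in TG. COL1A1 (620 and 354 CPM) and COL3A1 (2151 and 1309 CPM), the fibrillar collagens, were lower. The list's median turned to -0.17 with mixed nuclei kept and to -0.13 with each library clustered on its own. Insulin signalling genes had 1 member higher, 6 lower and 15 neither (median -0.33). The insulin receptor substrates IRS2 and IRS1 measured 105 and 31.7 CPM and 139 and 46.2 CPM, the receptor IGF1R 1327 and 490 CPM, and the transcription factor FOXO3 716 and 342 CPM. This list was at percentile 3.82 with nuclei thinned to 1000 UMIs. Markers of other classes were higher in TG fibroblast-like nuclei, with 12 of 15 vascular endothelial markers higher, 1 lower and 2 neither (median 1.98) and 5 of 6 T or NK markers, 0 and 1 (median 2.49). Of 8 endocardial markers, which include SMOC1 and MEOX1, 5 were higher, 2 lower and 1 neither (median 1.04). Of 7 capillary markers 6 were higher, 0 lower and 1 neither (median 2.85). Arterial, pericyte, smooth muscle and macrophage markers also stood above percentile 99. WT fibroblasts came almost all from cluster 2 and TG fibroblasts from cluster 28.

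Vascular endothelial-like nuclei carried more interferon-induced transcripts in TG. IFI6 (chromosome 6, 84852782 to 84858072) was at 73.0 CPM in WT and 471 CPM in TG, 6.45 times higher (5.79 to 7.20). The antiviral genes MX2, RSAD2 and ISG15 measured 55.6 and 220 CPM, 32.8 and 115 CPM, and 22.7 and 81.7 CPM. Of 25 interferon response genes 14 were higher, 1 lower and 10 neither (median 0.76, above percentile 99 under every alternative run on lists). Capillary markers were higher too, with 4 of 8 members higher, 1 lower and 3 neither (median 0.67). The carbonic anhydrase CA4 was at 141 CPM in TG, 3.14 times its WT level, GPIHBP1, which anchors lipoprotein lipase, at 66.5 and 133 CPM, and BTNL9 at 101 and 191 CPM. The fatty acid carriers FABP4 and CD36 were at 437 and 759 CPM and at 1935 and 2820 CPM. Of markers of other classes, 6 of 8 T or NK markers were higher, 0 lower and 2 neither (median 1.55), and 5 of 10 lymphatic endothelial markers, 1 and 4 (median 0.82). Of 9 arterial markers 4 were higher, 3 lower and 2 neither (median 0.45, and 0.23 with percentile 98.32 when mixed nuclei were kept). SOX17 (19.3 and 46.1 CPM) and HEY1 (21.1 and 48.0 CPM) were higher and VEGFC (586 and 371 CPM) and DLL4 (37.3 and 21.1 CPM) lower. Of 8 endocardial markers 1 was higher, 5 lower and 2 neither (median -0.61, and -0.33 with percentile 2.39 when each library was clustered on its own). Also higher in TG were the protease inhibitor SLPI (83.9 and 331 CPM), RAMP3, a partner of the adrenomedullin receptor (22.3 and 106 CPM), the potassium channel KCNN2 (155 and 541 CPM) and RGS7 (13.8 and 133 CPM). The RGS7 log2 ratio of 3.28 came to 0.40 with each library clustered on its own, and that of KCNN2 from 1.80 to 0.88 with mixed nuclei kept. CRYAB, HSPB6, HSPB7, TCAP and DHRS4 met the rule with levels alike over the 5 classes in TG, TCAP between 645 and 753 CPM.

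Matrix genes were lower in TG endothelium. COL21A1 (chromosome 7, 29414851 to 29609039) was at 90.2 CPM in WT and 2.15 CPM in TG, 41.9 times higher in WT. LTBP2 was at 88.6 and 4.52 CPM and FN1, fibronectin, at 156 and 35.2 CPM. NTM, not a matrix gene, was at 179 and 7.33 CPM. Of 39 extracellular matrix genes 6 were higher, 11 lower and 22 neither (median -0.38). THBS1 (139 and 30.7 CPM) and COL14A1 (44.4 and 9.70 CPM) were lower, and COL12A1 (5.68 and 17.7 CPM) higher. Lower as well were the calcium release channel RYR3 (72.2 and 5.82 CPM), ASB5 (62.5 and 7.22), the potassium channel KCNN3 (112 and 21.2), GNA14 (66.3 and 12.8), PLA2G4A (182 and 46.1), the apelin receptor APLNR (80.5 and 19.5), NREP (96.7 and 25.5) and PLEKHA6 (70.0 and 18.4). Fatty acid uptake and oxidation genes had 11 of 25 members higher, 0 lower and 14 neither (median 0.54). FABP3 (71.8 and 209 CPM), ACADM (88.8 and 227 CPM), ACADL (31.0 and 73.1 CPM) and HADHB (71.2 and 129 CPM) led that list, at levels alike over classes in TG. With each library clustered on its own, the fatty acid list was at 0.06, the matrix list at -0.10 with percentile 2.27, and the sarcomere list turned to -0.38. Clusters 5 and 7 held nuclei of both libraries, cluster 20, led by SLPI and GJA5, 101 WT and 703 TG nuclei, and cluster 27, led by COL23A1, MYRIP and RYR3, 87 WT and 0 TG nuclei. LTBP2 and KCNN3 were also among the leading genes of cluster 27. Whether RYR3, LTBP2 and KCNN3 were lower in TG because that cluster was absent there was not tested.

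Macrophage-like nuclei of TG carried transcripts of lipid-associated macrophages that were rare in WT. APOE, a lipid transport protein (chromosome 6, 51373113 to 51375333), had 9 UMIs in WT (1.54 CPM) and 322 in TG (220 CPM), 143 times higher in TG (74.3 to 315). SPP1, osteopontin, had 0 UMIs in WT and 38 in TG (25.9 CPM), at least 50.6 times higher against the limit of 3 counts. TREM2, a lipid receptor, was at 21.8 CPM in TG and GPNMB at 76.4 CPM. Of 12 measured members of this list 9 were higher, 0 lower and 3 neither, with a median log2 ratio of 2.22, above percentile 99 under every alternative run on lists. The list also stood above percentile 99 in cardiomyocyte, vascular endothelial and lymphatic endothelial-like nuclei. With mixed nuclei kept it was at 0.22 in vascular and 0.30 in lymphatic endothelial-like nuclei, no longer above percentile 99. APOE, SPP1, TREM2 and GPNMB were 10.9, 9.32, 67.5 and 3.84 times as high in TG macrophages as in the highest of 4 other TG classes. These were fibroblast, vascular endothelial, lymphatic endothelial and T or NK-like nuclei, and the remaining classes were not part of this comparison. The higher members CD36, CD9, FABP5, LGALS3 and LPL were not above those 4 classes. CD9 measured 3.76 and 40.2 CPM and FABP5 28.0 and 153 CPM. CD163, the haemoglobin scavenger receptor, was at 2580 and 5358 CPM (log2 ratio 1.05, and 0.39 with mixed nuclei kept). Of 14 resident macrophage genes 6 were higher, 1 lower and 7 neither (median 0.39), with TIMD4 at 4.44 and 16.4 CPM, CD209 at 45.6 and 92.1 CPM and IGF1 at 522 and 237 CPM. With mixed nuclei kept this list turned to -0.21, and with each library clustered on its own it was at 0.09, percentile 66.96. Interferon response genes had 11 of 22 members higher, 1 lower and 10 neither (median 0.88), with IFI6 at 22.6 and 175 CPM, MX2 at 32.6 and 131 CPM, MX1 at 12.5 and 42.3 CPM and OAS2 at 57.2 and 141 CPM. In TG vascular endothelial-like nuclei IFI6, MX2 and OAS2 were higher than here, at 471, 220 and 250 CPM, and MX1 lower, at 30.1 CPM. Markers of other classes were higher in TG macrophages too, with 7 of 13 fibroblast markers higher, 0 lower and 6 neither (median 1.07), 4 of 6 lymphatic endothelial markers, 0 and 2 (percentile 99.59) and 5 of 6 smooth muscle markers, 0 and 1 (median 1.36). Of 11 endothelial lipid transport genes 8 were higher, 0 lower and 3 neither (median 1.46), and the median turned to -3.20 with the library-wide profile subtracted. By size alone NBEA (9.74 and 218 CPM), ENPP1 (172 CPM in TG, 15.5 times its WT level) and GOLM1 (18.3 and 259 CPM) were also higher in TG. The zinc transporter SLC30A2 had 440 UMIs in WT (75.2 CPM) and 0 in TG, at least 36.7 times higher in WT. ATRNL1 (856 and 60.0 CPM), C8orf34 (490 and 50.5 CPM) and ASB5 (96.5 and 8.19 CPM) were lower in TG too. Both libraries drew this class from cluster 1 alone. With mixed nuclei kept, the log2 ratio of NBEA was 1.91 and that of ENPP1 0.54, against 4.49 and 3.95.

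Lymphatic endothelial-like nuclei, from cluster 9, differed most in VAT1L, with 2 UMIs in WT and 681 in TG (379 CPM), 918 times higher in TG (253 to 7596). FSTL4, a follistatin-like gene, had 3 UMIs in WT and 212 in TG (118 CPM), 191 times higher (64.3 to 931). Interferon response genes had 9 of 22 members higher, 0 lower and 13 neither (median 0.43), with MX2 at 0.825 and 39.5 CPM, ISG15 at 3.30 and 15.6 CPM, MX1 at 2.89 and 12.8 CPM and RSAD2 at 3.71 and 14.5 CPM. All 4 were higher in TG vascular endothelial-like nuclei than here. Markers of other classes were further apart, with 7 of 7 capillary markers higher, 0 lower and 0 neither (median 2.88), 7 of 7 pericyte markers, 0 and 0 (median 1.56), 7 of 13 fibroblast markers, 0 and 6 (median 1.14) and 5 of 13 macrophage markers, 0 and 8 (median 0.74). Lower in TG were PLD5 (348 and 80.1 CPM), the stress gene NUPR1 (172 and 36.7 CPM), the transcription factor NFATC2 (183 and 58.4 CPM) and ASB5 (61.1 and 7.23 CPM). LYVE1, the hyaluronan receptor that marks lymphatic vessels, was alike at 960 and 926 CPM. SPAG11 (2.06 and 50.1 CPM) was higher in TG, as was ANKRD1 (88.3 and 529 CPM), a muscle gene alike over classes. With mixed nuclei kept the interferon list was at 0.22, percentile 97.67, and with each library clustered on its own at 0.26, percentile 98.57.

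T or NK lymphocyte-like nuclei, from cluster 8, carried more cell cycle transcripts in TG. CENPE and CENPF, which act at the kinetochore, measured 26.3 and 133 CPM and 32.8 and 144 CPM, ASPM, a spindle protein, 11.8 and 55.2 CPM, and the topoisomerase TOP2A 33.3 and 115 CPM. Of 7 measured cycling markers 6 were higher, 0 lower and 1 neither (median 1.78, above percentile 99 under every alternative run on lists). In macrophage-like nuclei 4 of 7 were higher, 0 lower and 3 neither (median 1.44, percentile 99.56). Markers of other classes were higher in TG lymphocytes as well, with 11 of 14 fibroblast markers higher, 0 lower and 3 neither (median 1.58) and 8 of 9 pericyte markers, 1 and 0 (median 1.59). All 7 smooth muscle markers were higher, 0 lower and 0 neither (median 1.41), and 6 of 8 macrophage markers, 0 and 2 (median 1.24). Of 14 T or NK markers 2 were higher, 5 lower and 7 neither (median -0.34, percentile 5.29). DLG2, a scaffold protein, was at 79.5 and 899 CPM (log2 ratio 3.50, and 2.47 with mixed nuclei kept), and PBX4 at 5.91 and 52.3 CPM. THSD7B (1290 and 262 CPM), the kinase PRKCA (716 and 140 CPM), CDH4 (70.9 and 7.75 CPM) and ASB5 (73.1 and 4.84 CPM) were lower in TG. ASB5 was low in all 5 of these classes of TG, between 4.84 and 8.83 CPM, against 49.9 to 96.5 CPM in WT. Such levels, alike over classes within each library, do not tell free RNA from expression in these classes. DHRS4 (11.3 and 89.1 CPM) and CKMT2 (32.8 and 211 CPM) were higher in TG at levels alike over those classes. Of the fixed genes highest here, NPPB, the B-type natriuretic peptide, had 15 and 16 UMIs, a log2 ratio of 0.94 (-0.17 to 2.06). MYH7 was at 1214 and 4317 CPM, highest here in TG only, since WT cardiomyocytes were at 2626 CPM. NPPB is on the cardiac stress list and MYH7 is a cardiomyocyte marker, and free RNA is not excluded as their source here.

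Pericyte-like nuclei, from cluster 10, had lower levels of their own markers in TG per count of the class, while carrying the most cardiomyocyte marker signal of any class outside cardiomyocytes. RGS5, a regulator of G protein signalling, was at 1821 and 599 CPM, EGFLAM at 1850 and 646 CPM, the guanylate cyclase subunit GUCY1A2 at 1683 and 749 CPM and the potassium channel KCNJ8 at 682 and 304 CPM. Of 12 pericyte markers 1 was higher, 11 lower and 0 neither (median -1.17). Subtraction of the library-wide profile left 42.2% of WT and 9.52% of TG counts in this class, but at least 77.4% of those of each of the 4 named markers. Over that smaller total the 4 turned, to log2 ratios of 0.48, 0.54, 0.93 and 0.70, so their direction depended on the denominator. The cardiomyocyte genes NRXN3 (2.79 and 243 CPM), LRP1B (30.7 and 1233 CPM), GRIA1 (5.58 and 224 CPM) and SYT14 (2.79 and 72.1 CPM) led those higher in TG. Droplets that also hold a cardiomyocyte nucleus are not excluded as their source. HBB, a haemoglobin chain of red cells, was at 2281 and 245 CPM (log2 ratio -3.22, and -1.74 with each nucleus weighted equally). TOX3 had 105 UMIs in WT and 1 in TG, SH3RF2 was at 131 and 10.5 CPM and ADAM22 at 365 and 54.6 CPM. Of 32 extracellular matrix genes 3 were higher, 19 lower and 10 neither (median -0.79). The basement membrane collagens COL4A1 and COL4A2 were at 323 and 124 CPM and at 687 and 267 CPM, the crosslinking enzyme LOXL2 at 61.4 and 12.8 CPM and COL8A1 at 2.79 and 40.1 CPM. LPL, lipoprotein lipase, was at 1542 and 1213 CPM, and turned to a log2 ratio of 0.98 on subtraction. Of 12 clock genes 0 were higher, 6 lower and 6 neither (median -0.79, percentile 0.17), and the median was -0.20, percentile 28.61, with nuclei thinned to 1000 UMIs. The matrix list was at -0.36, percentile 4.69, with nuclei thinned to 1000 UMIs.

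Smooth muscle-like nuclei, from cluster 11, had lower matrix and immediate early transcripts in TG. COL12A1 (chromosome 1, 90744409 to 90875127) was at 654 CPM in WT and 21.5 CPM in TG, 30.4 times higher in WT. TNC was at 655 and 71.7 CPM, COL3A1 at 1212 and 158 CPM, THBS1 at 1767 and 471 CPM and CCN2 at 826 and 333 CPM. Of 34 extracellular matrix genes 4 were higher, 20 lower and 10 neither (median -0.97). Of 20 immediate early and heat shock genes 5 were higher, 11 lower and 4 neither (median -1.48). ATF3 was at 1253 and 138 CPM, the AP-1 subunit JUN at 386 and 48.4 CPM, and the chaperones DNAJB1 and HSPH1 at 173 and 7.17 CPM and at 186 and 17.9 CPM. Of 11 pericyte markers 8 were higher, 1 lower and 2 neither (median 0.98), and of 10 smooth muscle markers 0 were higher, 4 lower and 6 neither (median -0.31, percentile 17.79). The matrix and immediate early lists stayed below percentile 1 under every alternative that gave them a value. Inflammatory genes had 5 of 9 members higher, 0 lower and 4 neither (median 1.10), with the chemokine CXCL2 at 5.07 and 78.8 CPM, IL1R1 at 63.8 and 167 CPM, STAT3 at 107 and 228 CPM and NFKBIA at 12.3 and 34.0 CPM. This list was at 0.62, percentile 91.92, with nuclei thinned to 1000 UMIs. MAP3K8 (7.97 and 124 CPM), the urate carrier SLC2A9 (1.45 and 55.5 CPM) and SPAG11 (2.17 and 71.7 CPM) were higher in TG. RERG (201 and 3.58 CPM), MAPK4 (396 and 16.1 CPM) and FBLN5 (233 and 7.17 CPM) were lower.

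Schwann or neural-like nuclei, from cluster 16, were the smallest class compared, with 167 WT and 130 TG nuclei. Interferon response genes were higher in TG, with 7 of 13 members higher, 0 lower and 6 neither (median 0.75). MX2 had 3 UMIs in WT and 42 in TG, IFI6 was at 50.3 and 226 CPM, OAS2 at 21.4 and 102 CPM, all 3 below their levels in TG vascular endothelial-like nuclei, and GBP1 at 31.4 and 76.1 CPM. GBP1 turned to a log2 ratio of -0.41 on subtraction of the library-wide profile, which left 5.69% of its TG counts. The list was at percentile 98.88 without the highest doublet scores. Markers of vascular endothelium were further apart, with 12 of 12 higher, 0 lower and 0 neither (above percentile 99), as were endothelial lipid transport genes, with 8 of 10 higher, 1 lower and 1 neither (median 2.41). Of 11 Schwann or neural markers 1 was higher, 6 lower and 4 neither (median -0.73, percentile 0.35). CDH12, a cadherin, had 171 UMIs in WT and 1 in TG, and LUZP2 had 47 and 1. NHS was at 138 CPM in WT, 6.28 times its TG level. ROBO2, at 779 and 172 CPM, came to a log2 ratio of -0.59 without the highest doublet scores. NRXN3 and FRZB, both higher in TG cardiomyocytes, had 0 UMIs in WT and 33 and 26 in TG, at least 17.5 and 13.8 times higher. KCTD8 had 1 and 27 UMIs, 43.0 times higher with an interval from 7.09 to 1762.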

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

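The test on shallow and deep nuclei was planned, as were the settings with a profile subtracted, nuclei thinned or weighted equally, mixed nuclei kept and each library clustered on its own. Every other test in this part, and the use of those settings to weigh an explanation, was chosen after the result had been seen.

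Several gene lists drew attention because they were higher in TG in some cell classes and lower in others. The differences between classes were not tested. Glycolysis had a median log2 ratio, TG over WT, of -0.46 in cardiomyocyte-like nuclei and of 0.60, 0.46 and 0.51 in fibroblast, macrophage and Schwann or neural-like nuclei. With nuclei thinned to 1000 UMIs it no longer stood above percentile 99 in macrophage (0.27) or Schwann or neural-like nuclei (0.50). In the latter it also did not with nuclei weighted equally (0.39) or without the highest Scrublet scores (0.42). Calcium handling and ion channels were at -0.53 in smooth muscle-like nuclei. In fibroblast, vascular endothelial, macrophage, lymphatic endothelial, T or NK and pericyte-like nuclei that list was at 0.66, 0.47, 0.95, 0.49, 0.93 and 0.41. With the library-wide profile subtracted it turned to -0.32, -0.31, -1.14, -0.64 and -1.58 in the first 5 of these. It turned to -1.33, -0.52 and -0.83 in vascular endothelial, macrophage and T or NK-like nuclei with each library clustered on its own. In smooth muscle-like nuclei it turned to 0.16 with nuclei thinned to 1000 UMIs and to 0.36 without the highest Scrublet scores. Extracellular matrix genes were at 0.14, 0.63 and 1.44 in fibroblast, macrophage and T or NK-like nuclei, and at -0.38, -0.79 and -0.97 in vascular endothelial, pericyte and smooth muscle-like nuclei. The macrophage median turned to -0.42 with the profile subtracted, and the fibroblast median to -0.17 with mixed nuclei kept and to -0.13 with each library clustered on its own. The vascular endothelial median was -0.10 with each library clustered on its own and the pericyte median -0.36 in thinned nuclei, neither below percentile 1. Resident macrophage genes were at 0.79 and 0.39 in fibroblast and macrophage-like nuclei and at -0.85 in Schwann or neural-like nuclei. The fibroblast median turned to -0.18 with the profile subtracted and the macrophage median to -0.21 with mixed nuclei kept. The Schwann or neural median was -0.27, not below percentile 1, with nuclei weighted equally. Cytoplasmic ribosomal protein genes were at 0.23, 0.51 and 0.25 in fibroblast, smooth muscle and Schwann or neural-like nuclei. In vascular endothelial, lymphatic endothelial, T or NK and pericyte-like nuclei they were at -0.51, -0.46, -0.35 and -0.61. When each library was clustered on its own they were at -0.01, -0.12 and -0.15 in fibroblast, vascular endothelial and T or NK-like nuclei, none past percentile 1 or 99. In smooth muscle-like nuclei they were at 0.23 with nuclei weighted equally and 0.29 with nuclei thinned, and in Schwann or neural-like nuclei at 0.21, 0.29 and, without the highest Scrublet scores, 0.10, none above percentile 99. With the profile subtracted their T or NK median was -0.12, percentile 11.03. That median also lay just above percentile 1 with TMM factors (1.07), nuclei weighted equally (1.20) and at least 1000 genes per nucleus (1.06). The same held without the highest Scrublet scores (1.01) and with genes of at least 5 UMIs (1.05).

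Signals in nuclei that the comparisons leave out drew attention too. They exceeded the level that a count of 0 allows, and the difference between libraries was not tested. CXCL9 was at 32.5 CPM in WT and 65.6 CPM in TG in cluster 22, and SPP1 at 147 CPM in TG in cluster 18. ADIPOQ was at 58.7 and 86.4 CPM in cluster 12, and XCR1 at 532 and 165 CPM in cluster 4. These genes were picked because they lead those clusters.

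The higher OXPHOS levels outside cardiomyocytes in TG were alike over classes. The median member was 1.29 times as high in its highest as in its lowest of the fibroblast, vascular endothelial, macrophage, lymphatic endothelial and T or NK classes. Free RNA from cardiomyocytes would give such even levels. This ratio was also low in WT, at 1.49, and for unfolded protein response genes in TG, at 1.71. Even levels therefore do not tell free RNA from expression in these classes. The shallowest nuclei held 1.40 times the OXPHOS level of the deepest, which fits free RNA weighing more in shallow nuclei, but this also held in WT, from 1.28 to 1.66. With the library-wide profile subtracted the list stayed above percentile 99 in those 5 classes, at 1.55, 0.69, 1.23, 0.99 and 0.95, but turned to -0.25 in pericyte-like nuclei. In TG the muscle gene MYL2 was at 2617 CPM in fibroblast-like nuclei and at 1477 CPM in cardiomyocytes. Free RNA thus appears to differ in make-up from the subtracted profile. The subtraction therefore does not tell free RNA from expression, and free RNA of another make-up stays open. With 1 library per genotype, an effect of the genotype cannot be told apart.

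Lipid-associated genes in TG macrophage-like nuclei fell into 2 groups. Of the 9 higher members, 4 lay over 2 times their highest level in TG fibroblast, vascular endothelial, lymphatic endothelial and T or NK-like nuclei. For APOE, GPNMB, SPP1 and TREM2 this argues against free RNA from those 4 classes. Free RNA from other classes or from nuclei set aside was not tested. In TG SPP1 was at 147 CPM in the mixed cluster 18 and at 25.9 CPM in macrophage-like nuclei. The other 5 members, CD36, CD9, FABP5, LGALS3 and LPL, did not lie over 2 times that level. For them free RNA cannot be told apart from expression in macrophages, since both allow such levels. Without the highest Scrublet scores the list's median was 2.21, but 499 of the 502 TG nuclei stayed, so droplets with nuclei of 2 cells cannot be told apart either. Genotype cannot be told apart with 1 library per genotype.

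The higher share of vascular endothelial-like nuclei in TG was 2.65 times WT (2.48 to 2.84) with 2000 UMIs asked of both libraries. This floor removed mostly WT nuclei, and vascular endothelial-like nuclei were shallow there, with a median of 2717 UMIs. Fibroblast-like nuclei were shallower in TG than in WT, with medians of 2647 and 3971 UMIs. An equal floor is therefore not an equal cut, and the lowest total of barcodes is not excluded as a source. With mixed nuclei kept the ratio was 2.25 (2.13 to 2.37), which argues against the setting aside of mixed clusters. Fewer cardiomyocytes alone would raise the other classes alike. Fibroblast-like nuclei were not raised, at 0.735 (0.696 to 0.776) with 2000 UMIs asked of both libraries and 0.940 (0.899 to 0.983) with mixed nuclei kept. Because low totals cut the classes unequally, a piece of tissue of another make-up is not excluded. Genotype cannot be told apart with 1 library per genotype.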

How the results depend on the processing

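The alternatives with a floor of 2000 UMIs, with named nuclei as denominator and without the highest Scrublet scores were chosen after the data had been seen. No paired analysis was possible because there is 1 library per group, replicate 1 in each. Of the results on shares, 52 comparisons with an alternative stayed within the counting interval, 35 moved and 1 reversed. For list medians 1055 kept their side, 83 moved and 27 reversed, and for the 205 pairs of gene and class named in the text 1929 stayed within the interval, 447 moved and 9 reversed. The number of nuclei kept stayed within 1.5 times of its value in each library, with 17347 in WT and 14940 in TG at 200 genes per nucleus. With each library clustered on its own, no TG cluster took the pericyte or smooth muscle name, so these classes gave no value there. Depth limits genes with few counts, where intervals are widest.

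Shares moved as follows, with ratios TG over WT, and the cause was not tested except that a floor or a smaller denominator removes nuclei by construction. With at least 1000 genes per nucleus, ratios were cardiomyocyte 0.834, vascular endothelial 2.46, pericyte 1.21. With at most 1% mitochondrial UMIs, ratios were cardiomyocyte 0.907, fibroblast 0.575, vascular endothelial 2.74, lymphatic endothelial 0.574, T or NK lymphocyte 0.506. With at least 2000 UMIs per nucleus, ratios were cardiomyocyte 0.820, vascular endothelial 2.65, lymphatic endothelial 0.631, pericyte 1.27. Over named nuclei only, ratios were cardiomyocyte 0.955, fibroblast 0.848, vascular endothelial 2.24. Over named nuclei with at least 2000 UMIs, ratios were cardiomyocyte 0.908, fibroblast 0.815, vascular endothelial 2.94, macrophage 0.446, T or NK lymphocyte 0.884, pericyte 1.41. With mixed nuclei kept, ratios were fibroblast 0.940, vascular endothelial 2.25, macrophage 0.699, lymphatic endothelial 0.803, T or NK lymphocyte 0.865. With each library clustered on its own, ratios were vascular endothelial 1.79, macrophage 0.464, lymphatic endothelial 0.782, T or NK lymphocyte 0.876. At Leiden resolution 2, ratios were vascular endothelial 2.54, T or NK lymphocyte 0.609. With genes scaled within each library, ratios were macrophage 0.462, T or NK lymphocyte 1.02 (reversed), pericyte 1.49, smooth muscle 0.863.

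List medians and genes that lost their call, moved or reversed follow as log2 ratios, and the cause was not tested. Thinning and higher minima of UMIs leave fewer counts or genes by construction. By construction, subtraction of the library-wide profile left 9.52% of TG and 42.2% of WT pericyte counts and 29.8% and 55.2% of Schwann or neural counts. Of RGS5, EGFLAM, GUCY1A2 and KCNJ8 it left 94.1%, 92.9%, 95.9% and 77.4% in TG pericytes, so their ratios turned mainly because the total shrank more in TG. It left 0% of TG counts for HADHB in vascular endothelial and FABP5 in macrophage-like nuclei, and 0% of ROBO2 in both libraries of the Schwann or neural class, so those 3 values are not measured ratios. With at least 2000 UMIs per nucleus, smooth muscle lists were at insulin signalling -0.31. With mixed nuclei kept, fibroblast lists were at matrix -0.17 (reversed). Vascular endothelial: lipid-associated macrophage 0.22. Macrophage: calcium handling 0.22, oxidative stress 0.32, resident macrophage -0.21 (reversed). Lymphatic endothelial: interferon 0.22, antigen presentation 0.18, angiogenesis 0.18, lipid-associated macrophage 0.30. T or NK lymphocyte: angiogenesis 0.30. With each library clustered on its own, fibroblast lists were at matrix -0.13 (reversed), resident macrophage 0.47. Vascular endothelial: fatty acid 0.06, TCA cycle 0.07, cardiac stress -0.40 (reversed), sarcomere -0.38 (reversed), calcium handling -1.33 (reversed), matrix -0.10. Macrophage: fatty acid 0.21, TCA cycle 0.27, cardiac stress 0.17, sarcomere 0.01, calcium handling -0.52 (reversed), angiogenesis 0.43, resident macrophage 0.09. Lymphatic endothelial: interferon 0.26, antigen presentation 0.25, lipid-associated macrophage 0.20. T or NK lymphocyte: fatty acid 0.07, TCA cycle 0.10, cardiac stress 0.25, sarcomere 0.02, calcium handling -0.83 (reversed). With each nucleus weighted equally, cardiomyocyte lists were at oxidative stress 0.14. Lymphatic endothelial: antigen presentation 0.22. Smooth muscle: insulin signalling -0.25, calcium handling -0.03, inflammatory 0.79. Schwann or neural: glycolysis 0.39, resident macrophage -0.27. With nuclei thinned to 1000 UMIs, cardiomyocyte lists were at lipid-associated macrophage 0.50. Fibroblast: insulin signalling -0.24, angiogenesis 0.07, resident macrophage 0.54. Macrophage: glycolysis 0.27, oxidative stress 0.26, resident macrophage 0.25. Lymphatic endothelial: antigen presentation 0.19, angiogenesis 0.06. T or NK lymphocyte: TCA cycle 0.30, angiogenesis 0.82. Pericyte: matrix -0.36. Smooth muscle: TCA cycle 0.49, insulin signalling -0.34, calcium handling 0.16 (reversed), inflammatory 0.62. Schwann or neural: glycolysis 0.50, resident macrophage -0.51. With genes of at least 100 UMIs, cardiomyocyte lists were at lipid-associated macrophage 0.11. Fibroblast: matrix 0.07, angiogenesis 0.16. Macrophage: matrix 0.15, angiogenesis 0.10, oxidative stress 0.10, resident macrophage 0.15. Lymphatic endothelial: angiogenesis -0.03 (reversed). Smooth muscle: fatty acid 0.32, insulin signalling -0.38, oxidative stress 0.20. Schwann or neural: angiogenesis 0.22. With the library-wide profile subtracted, fibroblast lists were at TCA cycle 0.37, insulin signalling -0.30, calcium handling -0.32 (reversed), angiogenesis -0.28 (reversed), endothelial lipid transport -0.83 (reversed), resident macrophage -0.18 (reversed). Vascular endothelial: calcium handling -0.31 (reversed). Macrophage: fatty acid 0.04, TCA cycle 0.24, calcium handling -1.14 (reversed), matrix -0.42 (reversed), angiogenesis 0.32, endothelial lipid transport -3.20 (reversed), oxidative stress 0.20. Lymphatic endothelial: fatty acid -0.15 (reversed), TCA cycle 0.05, calcium handling -0.64 (reversed), antigen presentation 0.28, lipid-associated macrophage 0.45. T or NK lymphocyte: fatty acid 0.16, TCA cycle 0.22, calcium handling -1.58 (reversed), angiogenesis -0.60 (reversed), endothelial lipid transport -1.06 (reversed). Pericyte: fatty acid -0.38 (reversed), TCA cycle -1.44 (reversed), OXPHOS -0.25 (reversed), calcium handling 0.91. Smooth muscle: insulin signalling -0.53, calcium handling -0.76. Schwann or neural: fatty acid 0.43, TCA cycle 0.29, resident macrophage -1.98. Genes that reversed there were ROBO2 1.56 (Schwann or neural), LPL 0.98 (pericyte), HADHB -7.95 (vascular endothelial), FABP5 -4.85 (macrophage), RGS5 0.48 (pericyte), EGFLAM 0.54 (pericyte), GUCY1A2 0.93 (pericyte), KCNJ8 0.70 (pericyte), GBP1 -0.41 (Schwann or neural). Without the highest Scrublet scores, lymphatic endothelial lists were at antigen presentation 0.38. Smooth muscle: insulin signalling -0.23, calcium handling 0.36 (reversed). Schwann or neural: glycolysis 0.42, interferon 0.58. With genes of at least 5 UMIs, T or NK lymphocyte lists were at angiogenesis 0.85.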

Other observations

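Nuclei left out of the comparisons carried further types. Cluster 4, with 185 WT and 60 TG nuclei, was led by CLNK, XCR1 and FLT3, genes of conventional dendritic cells. XCR1 was at 532 CPM in WT (485 to 583) and 165 CPM in TG (121 to 220), and FLT3 at 581 and 521 CPM. Cluster 13, with 255 WT and 218 TG nuclei, was led by TBXAS1, thromboxane synthase, at 2253 and 990 CPM, and PLVAP at 665 and 539 CPM. Cluster 12, set aside as mixed, with 373 WT and 382 TG nuclei, was led by the fat cell genes ADIPOQ, at 58.7 and 86.4 CPM, and PLIN1, at 16.5 and 24.0 CPM.

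Cluster 18, with markers of macrophages and of vascular endothelium, held 81 WT and 335 TG nuclei. SPP1 had 0 UMIs there in WT and 220 in TG (147 CPM, 128 to 168), and TGM3 was at 8.84 and 163 CPM. Cluster 22, with markers of fibroblasts and of vascular endothelium, held 74 WT and 381 TG nuclei. IFI6 was at 85.5 and 329 CPM there, CXCL10 at 68.4 and 104 CPM and CXCL9 at 32.5 and 65.6 CPM.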
